A study of Homo sapiens with 18 samples.

How the data were processed

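Gene counts and TPM values were taken as deposited for 18 libraries of HMC3 cells. Per the labels' protocols, 1 well gave 1 sample, ribosomal RNA was depleted, and strand-specific libraries were made from equal amounts of RNA. Per the submitters' processing notes, the tools were STAR 2.5.2b, HTSeq and R 4.3.1 on hg19 (GRCh37.p13). The version of HTSeq and its strand setting are not given in the sources used here. The count table holds whole-number counts per gene that the authors did not normalize, and the TPM table holds the authors' deposited TPM values.

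The count table has 48135 genes and 5 summary rows, which were kept out of library sizes and tests. Reads outside genes made up 12.3% to 22.3% of each library, ambiguous reads 6.21% to 7.86%, unaligned reads 4.74% to 8.22% and reads with several alignments 3.58% to 4.69%. No count was seen in any library for 620 genes. Symbols came from the deposited TPM table for 47871 genes and from a table of gene names for 255, and 9 had none. Chromosomes and gene types were taken from GENCODE v29 on GRCh38 by Ensembl identifier for 39559 genes, and coordinates are given in that build, which is not the build of the counts. Gene counts ran from 22817702 to 38727047 per library.

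Groups came from the sample titles. The comparison of 2 deletion with 4 control clones used counts summed over the 3 libraries of each clone, filterByExpr, TMM normalization and the robust edgeR quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Single clones were compared in one edgeR fit to the 18 libraries with a coefficient per clone. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. CPM values use TMM-scaled library sizes, and a standard error is the size of the log2 fold change over the square root of F. Lists of at least 5 tested genes were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry. Named genes are TSPAN14, the 10 largest rises and 10 largest falls with an average log2 CPM of at least 1 and all deletion libraries on one side of all control libraries, tested genes near TSPAN14, and up to 4 members of each list by smallest p. Single-clone comparisons take the 5 largest rises and falls by the same criteria, and each control clone 1 of each. Small RNAs, genes without a symbol and genes of the Y chromosome were passed over. HOXC9 and the other genes at 0 counts are given as bounds at 3 counts.

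Wells with the same replicate number deviated together. In all 45 pairs of libraries with the same number, from different clones, deviations from the clone means correlated at 0.314 to 0.717, against -0.55 to 0.201 for the 90 pairs with different numbers. The numbers therefore pair the samples, and the pairing comes from the data, since the labels name no batch. Libraries with number 3 had 0.441% to 0.563% of gene counts in the small RNA 7SK, against 2.11% to 3.07% in the others. None of the 18 pairs of wells within a clone agreed within sampling noise, and pairs across clones were not compared in this way.

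The fits were tested on simulated data with 200 genes changed. For the comparison of clone sums over 24113 genes, 47.8% of 1.5-fold, 59.7% of 2-fold and 92.4% of 4-fold changes were recovered, and 19 unchanged genes were called, 12.5% of the calls and above the nominal 5%. For deletion clone 1 against the control clones over 20051 genes, the shares were 23.9%, 55.2% and 80.3%, and for deletion clone 1 against deletion clone 2 over 20063 genes 8.96%, 55.2% and 84.8%. Unchanged genes made up 7.83% and 5.71% of the calls in these 2 comparisons. The simulated wells were independent, without the shared deviation by replicate number, and far fewer genes were changed than were called in the data. These shares therefore need not hold for the data. Alternatives were other size factors, DESeq2 1.42.0, limma-voom, no filter, other units of replication, the replicate block, TPM values, a 1.5-fold threshold and leaving out each clone or library. Alternatives by replicate number, the sums without number 3 or without deletion clone 2 replicate 2, and the 1.5-fold threshold for the clone sums were added after seeing the data. Figures were drawn with matplotlib.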

Results

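RNA sequencing was run on HMC3 cells, an immortalized human microglial line. Cells had received Cas9 and a pair of guides flanking a short enhancer region of TSPAN14 that holds 3 candidate Alzheimer disease variants, and single cells were grown into clonal lines. The 18 libraries came from 6 clones with 3 wells each. There were 2 clones with a homozygous deletion, 3 clones with a non-targeting guide (NTC1, NTC2 and NTC3) and 1 clone with the vector alone. The deposited counts held 48135 genes, and each library had between 22817702 and 38727047 counts in genes. The clone carries the genotype, so counts were summed per clone and 2 deletion clones were compared with 4 control clones. Wells of one clone are not separate edits, and p-values from single-clone comparisons measure only the spread between wells.

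The first question was whether removal of the enhancer region goes with a change in TSPAN14 (ENSG00000108219.10), which encodes a tetraspanin that helps the protease ADAM10 to mature and reach the cell surface. The gene lies on the forward strand of chromosome 10, from 80454166 to 80533123 in GRCh38, and is annotated as protein coding. TSPAN14 was 3.52-fold lower in the deletion clones, at 43.8 ± 4.27 CPM (counts scaled by library size; SD, n = 2 clones) against 153 ± 4.25 CPM (SD, n = 4 clones). The log2 fold change was -1.81 with a standard error of 0.057 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.81e-12). Every deletion library, from 34.7 to 49.9 CPM, lay below every control library, from 106 to 197 CPM. An exact permutation test over the 15 ways to pick 2 of 6 clones gave p = 0.0667 one-sided, the smallest value that design allows, and 0.133 two-sided. The reduction appeared in both lines, with log2 fold changes of -1.76 in deletion clone 1 and -1.95 in deletion clone 2, and TSPAN14 was not called between them (log2 difference 0.19, adjusted p = 1). In the wells that share replicate number 1, 2 or 3, the deletion clones had 25%, 23.8% and 38.7% of the control level. The higher share for number 3 came with lower control levels, 106 to 114 CPM against 164 to 197 CPM for the other numbers. In the deposited TPM values it came more from the deletion libraries, at 9.93 and 7.36 TPM for number 3 against 5.75 to 6.29 for the others, with control levels of 22.5 to 23.6 against 24.9 to 29.7.

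**Figure D1:**
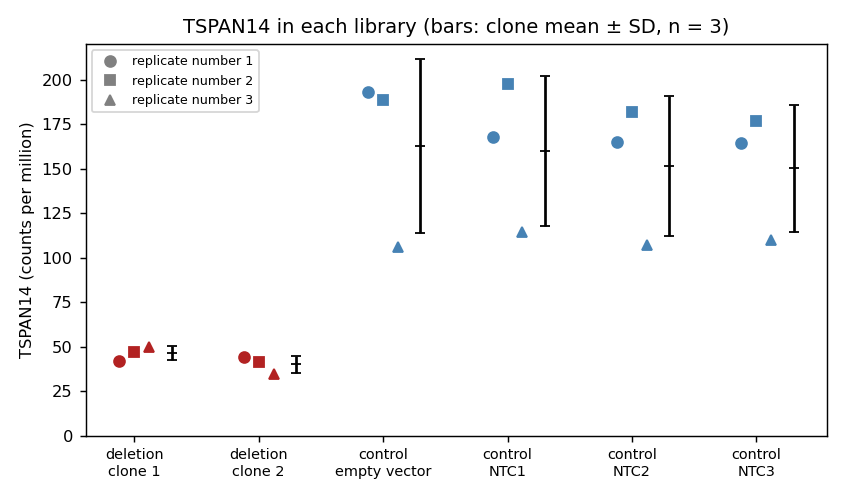
TSPAN14 in CPM for each of the 18 libraries, with marker shape giving the replicate number and black bars giving each clone's mean and SD over 3 wells. The 6 deletion libraries sit between 34.7 and 49.9 CPM and the 12 control libraries between 106 and 197 CPM.

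Across the transcriptome, 4557 genes were higher and 4797 were lower in the deletion clones among 24646 tested (edgeR, adjusted p below 0.05), which is 38% of the tested genes. The largest rises were in GALNT13, a glycosyltransferase, and DCLK1, a microtubule-associated kinase. GALNT13 stood at 11.7 ± 0.229 CPM against 1.21 ± 0.382 CPM, 9.68-fold higher, and DCLK1 at 26.2 ± 4.89 CPM against 3.31 ± 0.746 CPM, 7.89-fold higher (SD, n = 2 and 4 clones). CCDC81 (7.12-fold), the cGMP-dependent kinase PRKG1 (6.77-fold), protocadherin PCDH7 (5.97-fold), the retinoic acid hydroxylase CYP26B1 (5.4-fold), WNK2 (4.75-fold), the somatostatin receptor SSTR1 (4.6-fold), KIF26A (4.02-fold) and KLF15 (3.81-fold) also rose.

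The falls were larger than the rises and several reached near silence. EMC10, a subunit of the membrane protein insertion complex of the endoplasmic reticulum, fell from 15.1 ± 0.9 CPM in the control clones to 0.0776 ± 0.00437 CPM, and DNAJC15, a mitochondrial co-chaperone, from 11.4 ± 1.43 to 0.0891 ± 0.0207 CPM (SD, n = 4 and 2 clones). The glypican GPC4 fell from 23.7 ± 8.99 to 0.131 ± 0.01 CPM, and APBB1IP, a partner of the GTPase Rap1, from 7.18 ± 0.579 to 0.0346 ± 0.0489 CPM. HOXD-AS1, CA8, PDPN and HOXD10 had between 4 and 6 counts in all 6 deletion libraries, against 5.07, 3.4, 4.09 and 4.72 CPM in the control clones. TSPYL5 and G0S2 had 2 counts each in the deletion clones, which puts them 293-fold lower (counting interval 81 to 2420) and 258-fold lower (71.1 to 2130). These intervals cover counting error only. Reads of HOXD-AS1 and of genes that overlap it cannot be told apart if counting ignored strand, a setting not given in the sources used here.

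Most changes were modest, since 6062 of the 9354 called genes differed by less than 1.5-fold. At least 2-fold, 315 genes were higher and 1499 lower. In 2021 called genes all 6 deletion libraries lay on one side of all 12 control libraries. Chance would give this for 0.0108% of genes if the 18 wells were exchangeable, which wells of one clone are not. Counted by clone, both deletion clones lay on one side of the 4 control clones in 12980 of the 24646 tested genes (52.7%), against 13.3% by chance. Tested against a 1.5-fold change, a threshold chosen after seeing the data, 272 genes were higher and 1120 lower. On the deposited TPM values the balance moved to 2345 higher and 5955 lower. Fits to the 18 libraries in place of clone sums gave 6141 calls with wells as replicates and 5435 with one coefficient per clone. They gave 9184 with the clone as a random block and 10420 with one coefficient per clone and the replicate block. The random block had a within-clone correlation of -0.228, so it did not treat wells of one clone as alike. None of these fits therefore takes the clone as the unit. Within replicate number 1, 2 and 3 alone, 5223, 8450 and 6517 genes were called.

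Of 28 gene lists fixed before the data were examined, camera with a preset correlation called 16, with 13 lower and 3 higher. Over all tested genes 18.5% were higher and 19.5% lower, which is the background for the counts of list members below. With an estimated correlation camera called 0, with 3 lists at an unadjusted p below 0.05, and fry called 22. Camera compares a list with the other tested genes, while fry asks only whether genes of the list changed. With 38% of all tested genes called, a fry call does not set a list apart. Camera with the preset correlation called up to 16 lists when other pairs of the 6 clones were compared with the remaining 4. The pair with 16, NTC1 and NTC2, was compared with a group that held both deletion clones. It therefore carries the deletion difference and is no background. Pairs of 1 deletion and 1 control clone gave 2 to 10 lists. These splits do not rank the list calls against the per-gene counts, and the list calls depend on how camera was run. The correlation alone does not account for the lost calls. Immediate early and complement genes had estimated correlations of -0.013 and -0.009, below the preset 0.01, and still lost their calls. The adjusted p of 0.197 given for many lists below is a tied value after adjustment, not particular to one list.

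Most tested genes of the interferon response and all 5 tested MHC class II genes were lower in the deletion clones. Of 33 tested interferon genes, 25 fell and none rose, and 31 fell when adjusted over the list alone, with a median log2 fold change of -2.34 (camera adjusted p = 7.33e-12; adjusted p = 0.326 with an estimated correlation). B2M, the light chain of MHC class I, stood at 147 ± 7.05 CPM against 294 ± 19.4 CPM (SD, n = 2 and 4 clones). HLA-B was 3.61-fold, HLA-C 2.45-fold and the immunoproteasome subunit PSMB8 5.08-fold lower. All 5 tested MHC class II genes fell, with HLA-DPB1 5.11-fold, HLA-DPA1 6.5-fold, HLA-DMA 2.68-fold and CD74 3.23-fold lower (adjusted p = 0.000395; adjusted p = 0.197 with an estimated correlation). HLA genes share sequence, so reads that align to several of them may be missing from their counts, since such reads were tallied apart.

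Among cytokines and NF-kB targets, 23 of 28 fell and 2 rose, with a median of -1.12 (camera adjusted p = 3.72e-08; adjusted p = 0.197 with an estimated correlation). Interleukin IL6 was at 1.49 ± 0.108 CPM against 5.84 ± 0.248 CPM. CXCL5, a neutrophil chemokine, was 12.5-fold, the NF-kB inhibitor TNFAIP3 2.14-fold and IL32 3.5-fold lower. In the complement list 7 of 16 fell and 1 rose (adjusted p = 0.0239; adjusted p = 0.197 with an estimated correlation), and C3 was 6.52-fold lower.

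HOX genes, which pattern the body axis, showed the largest shift of any list. Of 20 tested, 17 fell and none rose, with a median of -3.17, or -3.15 with the genes at 0 counts set to their bounds (camera adjusted p = 7.49e-08; adjusted p = 0.197 with an estimated correlation). HOXC8 had 3 counts in the deletion clones and was 120-fold lower (counting interval 41 to 584), and HOXC10 had 1 count and was 95.9-fold lower (17 to 3810). HOXC9 had no count in either deletion clone and was at least 14.5-fold lower, against a floor of 3 counts over the group. HOXC6 was 11.4-fold lower. Clustered protocadherins moved the other way, with 9 of 15 rising and 1 falling (adjusted p = 0.000322; adjusted p = 0.197 with an estimated correlation). PCDHGB4 was 3.66-fold and PCDHB13 2.05-fold higher, although genes of these clusters share exons or sequence.

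Matrix and adhesion genes were mostly lower, with 22 of 35 falling and 2 rising (median -0.69, adjusted p = 5.15e-09; adjusted p = 0.197 with an estimated correlation). The integrin subunits ITGB3, ITGA1 and ITGA3 were 3.9-fold, 48.3-fold and 1.79-fold lower, and the membrane metalloprotease MMP14 1.75-fold lower. Of 22 tested mesenchymal, fibroblast and pericyte genes, 12 fell and 2 rose (adjusted p = 0.00118; adjusted p = 0.197 with an estimated correlation), among them the collagen genes COL6A1 (2.47-fold lower) and COL6A2 (1.91-fold lower). Markers of endothelium fell in 7 of 9 (adjusted p = 0.00255; adjusted p = 0.197 with an estimated correlation) and of epithelium in 8 of 9 (adjusted p = 0.000232; adjusted p = 0.197 with an estimated correlation), with TIE1 18-fold and KRT18 1.62-fold lower. Of the 7 endothelial falls, 5 were in genes below 1 CPM in the control clones. Summed counts of 3762 silent protein-coding genes were also lower in the deletion libraries, at 45.1 to 57 CPM against 67.4 to 89.4 CPM in the control libraries, apart from 193 CPM in deletion clone 2 replicate 2.

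The lists of protease partners, their substrates and Notch targets were not called by camera, while fry called the first and the last. A fry call does not set a list apart from other genes. In the list of ADAM10-regulating tetraspanins with ADAM10 and ADAM17, 3 of 13 rose and 5 fell (camera adjusted p = 0.343, fry adjusted p = 0.00124). TSPAN15 was 1.44-fold and TSPAN5 1.19-fold higher, while TIMP3, an inhibitor of metalloproteases, fell from 39.4 ± 2.9 to 1.3 ± 0.466 CPM. The 5 falls include TSPAN14 itself and TIMP3, and the other 3 were TSPAN33 (1.53-fold), ADAM17 (1.15-fold) and FRMD8 (1.15-fold), while ADAM10 did not pass (1.03-fold higher, adjusted p = 0.602). These 4 were named after their values were seen. ADAM10 substrates split into 11 that rose and 12 that fell of 31 (camera adjusted p = 0.655, fry adjusted p = 0.0786), with SORL1, a sorting receptor, 13.4-fold lower. Among Notch targets 9 of 15 fell and 4 rose (camera adjusted p = 0.0825, fry adjusted p = 0.00308), with HES1 2.79-fold and HEY1 2.49-fold lower and NOTCH3 1.35-fold higher. Of other tetraspanins 11 of 18 fell and 2 rose (adjusted p = 0.0123; adjusted p = 0.197 with an estimated correlation), and CD82 was 2.99-fold lower. Of these 11 falls, 6 were in genes of chromosome 12, whose genes had a median log2 fold change of -0.30 in each deletion clone, and CD63 was at -0.40.

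Of 35 tested Alzheimer risk genes, TSPAN14 included, 14 fell, 4 rose and 17 did not pass (adjusted p = 0.0301; adjusted p = 0.197 with an estimated correlation). ABI3, an actin regulator, was 18.9-fold lower and APH1B, a gamma-secretase subunit, 2.33-fold lower. Microglia and macrophage markers had 6 of 15 falling and 2 rising (camera adjusted p = 0.0769, fry adjusted p = 0.00182), with CD14 5.14-fold lower. Only 15 of the 33 markers of that list were tested. TMEM119, CX3CR1, SPI1, TYROBP and PTPRC were among those with too few counts to test, so these falls say little about microglial identity. Immediate early and dissociation genes rose in 12 of 24 and fell in 2 (adjusted p = 0.000134; adjusted p = 0.197 with an estimated correlation), with EGR1 1.45-fold and KLF4 1.94-fold higher. Cells were lifted with 1 of 2 enzymes and pellets were used fresh or frozen, and the labels do not say which sample had which. Cell cycle genes rose in 9 of 29 and fell in 3 (adjusted p = 0.0377; adjusted p = 0.55 with an estimated correlation), with E2F8 1.51-fold higher and CCNB1 1.28-fold lower. Glycolysis and hypoxia genes fell in 7 of 24 and rose in 1 (adjusted p = 0.0145; adjusted p = 0.335 with an estimated correlation). With 38% of all tested genes called, the number of called members does not set the cell cycle or glycolysis lists apart. Of the 13 mitochondrial mRNAs 0 passed by edgeR (camera adjusted p = 0.443), with 0 at an unadjusted p below 0.05 and 0 by DESeq2.

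**Figure D2:**
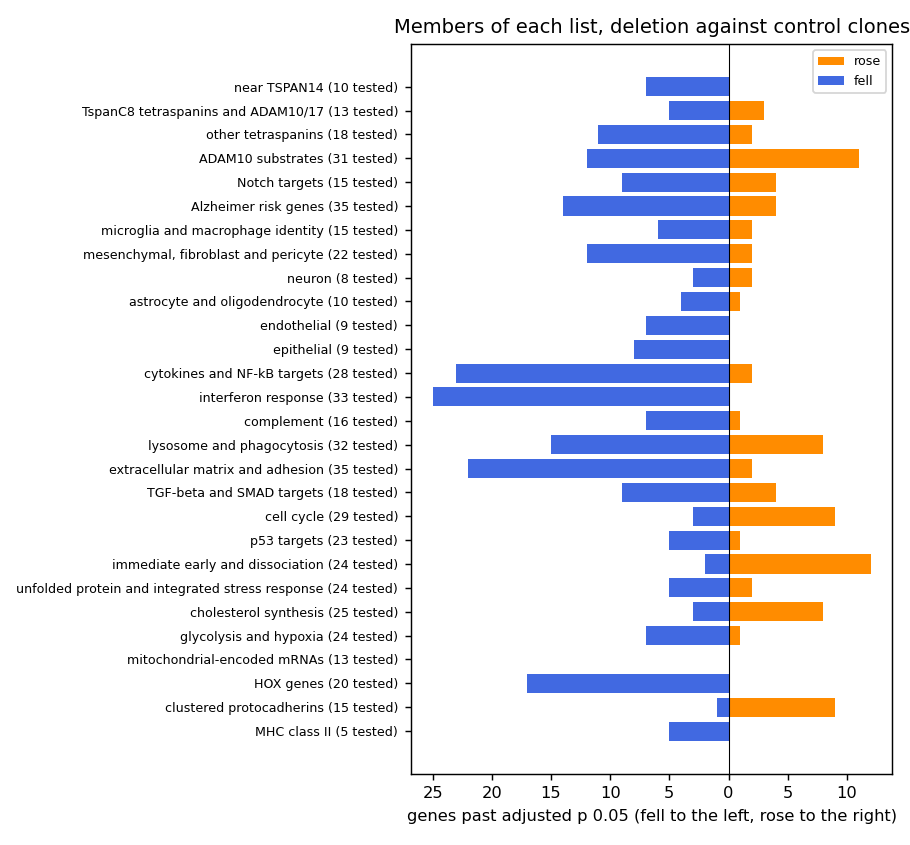
Number of tested members of each gene list that rose (orange, right) or fell (blue, left) in the deletion clones against the control clones at an adjusted p below 0.05. The interferon list has 25 falls and no rise, the HOX list 17 falls and no rise, and the protocadherin list 9 rises and 1 fall.

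A deleted enhancer can act on more than one gene nearby, so the genes around TSPAN14 were compared one by one. Of 10 tested, 7 fell and none rose, the same count when adjusted over the list alone, with a median log2 fold change of -0.29 (camera adjusted p = 0.00118; adjusted p = 0.197 with an estimated correlation). Among genes with an average log2 CPM of at least 1, 6 of 8 near genes were called, all lower. Of the other 361 genes of the long arm 258 were called, 130 higher and 128 lower. The share called thus does not set the near genes apart. TMEM254 was 1.85-fold lower (3.5 ± 0.167 against 6.45 ± 0.345 CPM) and the transcriptional coregulator ZMIZ1 1.47-fold lower (65.8 ± 4.1 against 96.2 ± 6.45 CPM; SD, n = 2 and 4 clones). ANXA11, PPIF, GHITM and ZCCHC24 were 1.2-fold, 1.21-fold, 1.24-fold and 1.13-fold lower. MAT1A had 2 counts in the deletion clones and was 15.1-fold lower (counting interval 4.01 to 127). GHITM, which starts at 84139440, was the one tested gene beyond the end of TSPAN14. EIF5AL1, PLAC9 and FAM213A did not pass, with log2 fold changes of -0.08, -0.42 and -0.04. With the clone as a random block over 18 libraries, a fit that did not treat wells of one clone as alike, 4 genes were called.

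**Figure D3:**
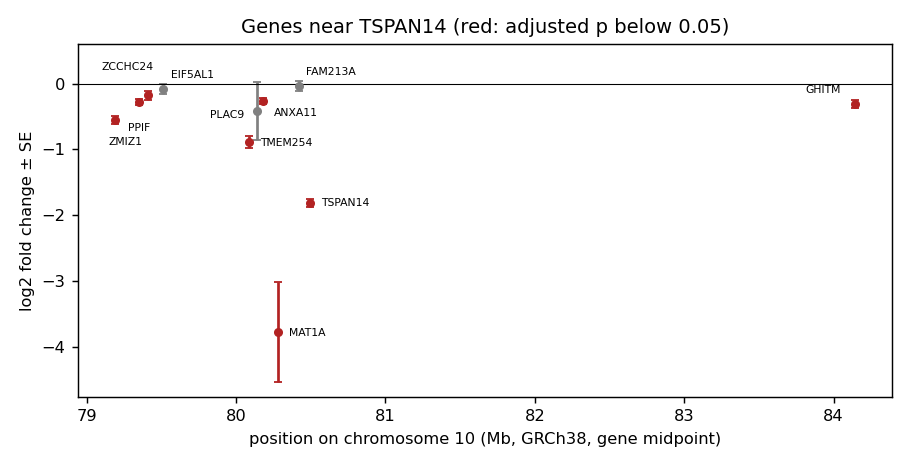
Log2 fold change, deletion over control clones, with its standard error, for TSPAN14 and the tested genes near it, placed by the midpoint of each gene on chromosome 10 in GRCh38. TSPAN14 lies at -1.81, MAT1A at -3.77 from 2 counts, and ZMIZ1 at -0.55.

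Each deletion clone was next compared with the 4 control clones on the 18 libraries, to see whether both lines carry the same changes. Deletion clone 1 differed at 3892 genes (1816 higher, 2076 lower) and deletion clone 2 at 3076 (1352 higher, 1724 lower) of 20528 tested. With the replicate number as a block the counts were 9082 and 8256. GALNT13, DCLK1, PRKG1 and CCDC81 were among the 5 largest rises in both lines, with GALNT13 10.1-fold higher in each. CYP26B1 was 6.93-fold higher in clone 1 and PCDH7 6.37-fold higher in clone 2. In clone 1, APBB1IP, PDPN, TSPYL5 and G0S2 had no counts and were at least 194-fold, 112-fold, 94.9-fold and 83.4-fold lower against a floor of 3 counts over the clone. In clone 2, EMC10 was 181-fold and GPC4 156-fold lower, and CXCL1, a chemokine with 1 count, was 256-fold lower (counting interval 45.9 to 10100). Without its replicate 1 or replicate 2, deletion clone 2 had 1963 or 1994 calls.

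Both lines shared 2597 calls in one direction, 1137 higher and 1460 lower, and 1 call in opposite directions. Independent lists of these sizes would share 120 higher and 174 lower. With a different pair of control clones for each line, 1870 to 2082 genes were shared. The fold changes of the 2 lines correlated across genes at 0.887, against 0.194 in 20 simulations of unchanged clones with the same controls, and genes are not independent replicates. Their covariance was 0.508 against 0.0186 simulated. With the replicate block, 6773 calls were shared, 3344 higher and 3429 lower.

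**Figure D4:**
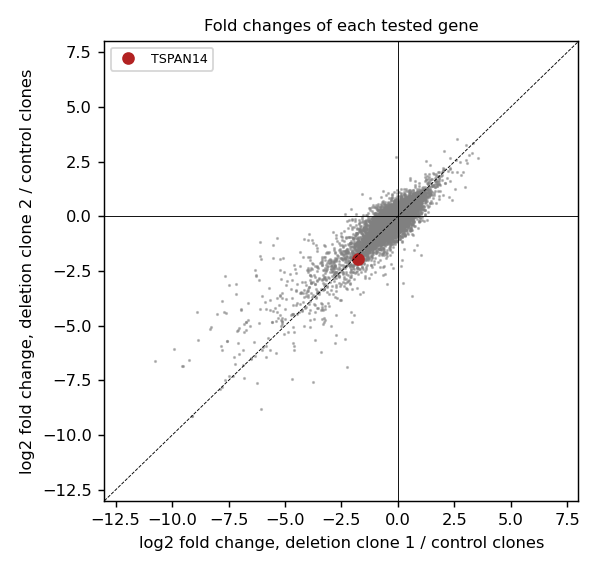
Log2 fold change against the 4 control clones for each of 20528 tested genes, deletion clone 1 on the horizontal and deletion clone 2 on the vertical axis, with the dashed line marking equal values. TSPAN14 lies at -1.76 and -1.95, and the correlation across genes is 0.887.

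The deletion clones differed from each other at 13 genes, 10 higher and 3 lower in clone 1, and at 376 with the replicate block. MGST2, an enzyme of the leukotriene pathway, was 7.01-fold, NPW 6.18-fold, ACN9 5.9-fold, AEBP1 2.71-fold and HSD17B12 2.11-fold higher in clone 1. SH3BGRL, FAM13A and ARHGAP44 were 4.09-fold, 2.64-fold and 1.99-fold lower in clone 1. The count was 4 without replicate 2 or replicate 3 of deletion clone 2, 6 without replicate 1 of deletion clone 1, 7 without its replicate 2, and 0 when only these 6 libraries were fitted.

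The control clones give the background for these counts. The empty vector clone differed from the 3 NTC clones at 3 genes, EPDR1 and ZFPM2 (log2 fold changes -2.75 and -1.42) and SLC7A3 (4.03). EPDR1 and SLC7A3 were named because the count was small, after their values were seen. With the replicate block 283 genes were called, and between 1 and 8 genes when single libraries were left out. NTC1, NTC2 and NTC3 each gave 0 calls by edgeR against the other 3 control clones, with 234, 171 and 158 genes at an unadjusted p below 0.05. The replicate block gave 23, 16 and 0 calls, and DESeq2 gave 1, 0 and 0. Over all tested genes the deletion clones lay 0.404 apart (root mean square log2 difference), the control clones 0.319 to 0.363 apart, and deletion from control clones 0.684 to 0.807.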

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

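The tests of a batch by calls within single numbers, of separate drift by genes off and by covariance, of a shared founder, of depth and of genomic DNA were chosen after the values they measure had been seen at least in part, and the other tests before.

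In 8 of 132 named genes 1 of the 4 control clones stood apart from the other 3, where chance flags about 1 group in 20. The gap over the range of log2 values was 0.941 for CYP26B1 and 0.868 for TSPYL5 in the empty vector clone (1.77 against 1.4 to 1.42 CPM, and 6.57 against 2.27 to 2.64 CPM). It was 0.907 for ERG in the same clone, 0.899 for CD63 and 0.847 for TEK in NTC3, 0.85 for NOTCH3 and 0.842 for CSPG4 in NTC2, and 0.941 for HSP90B1 in NTC1. The deletion clones differed from each other, by the edgeR test of the difference itself, in MGST2 (log2 2.81), NPW (2.63), ACN9 (2.56), AEBP1 (1.44), HSD17B12 (1.08), SH3BGRL (-2.03), FAM13A (-1.40) and ARHGAP44 (-0.99).

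Both deletion clones differed from the control clones at many genes, and from each other at 13, or 376 with the replicate block. They lay 0.404 apart in root mean square log2 difference, more than any 2 control clones (0.319 to 0.363). A batch that goes with the replicate number is argued against, because each clone has 1 library of each number and at least 5223 genes were called within each single number. That 94.6% of the called genes had one sign in all 3 numbers decides nothing, since they were called on the same libraries. Drift of each line on its own is argued against by the covariance of their fold changes, which was at least 0.493 with split controls and at most 0.0222 in simulated unchanged clones. The genes off in a deletion clone go against separate drift only if every gene is equally prone to loss, which was not measured. In both lines 12 were off, where independent loss would under that assumption give 0.023. Without deletion clone 2 replicate 2 these numbers were 20 and 0.063. The share of shared genes among the 25 off in either line, 48% with a binomial interval of 27.8% to 68.7%, does not decide between the lines' own losses and a founder. The reading of these genes changed 2 times after the outcome was seen. By the value alone, the rule at first, 48% lay under a bound of 50%, for separate drift and against a shared founder. It was then required that the whole interval pass the bound, and last the count expected under independent loss was set against drift. Background counts in deletion clone 2 replicate 2 were also tried as a reason for the share and were not one, since without that library it was 46.5% (20 of 43). Copy number of chromosome segments stays open for part of the genes, since 66.3% of the called genes with a position held after centring on 51 neighbours, and 86.9% of those changed at least 2-fold stayed so. An effect of the deletion cannot be told apart from a founder cell or culture history shared by the deletion lines or the control lines. The design gives each genotype its own lines, and the 12 genes off in both deletion clones could come from any of these. Handling that went with genotype was not tested and stays open, since the labels do not say which enzyme or pellet state each sample had.

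Of 10 tested genes near TSPAN14, 7 were lower in the deletion clones, 6 on one side and GHITM, the one gene tested on the other side, which starts at position 84139440 against the TSPAN14 end at 80533123. A shift of the whole long arm of chromosome 10 is argued against, because its other 361 genes had a median log2 fold change of -0.05 against -0.27 for the 8 listed genes with an average log2 CPM of at least 1 (interval of the difference -0.48 to -0.04). A downward shift of the surrounding megabases is argued against, because the 74 tested genes within 10 megabases outside the list had a median of 0.27 (0.08 to 0.42). These genes were themselves shifted upward, with 58 called, 40 higher and 18 lower. A regional change of another kind was not tested and stays open. A local effect of the deletion is one candidate and was not tested, since each genotype has its own lines. FAM213A, the tested gene nearest to TSPAN14, did not pass. The share called, 6 of 8 near genes against 258 of 361 others on the arm, does not set the near genes apart. The falls may also be part of the wider difference between the lines.

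Deletion clone 2 replicate 2 had counts in 36725 genes, against 28397 to 33272 in the other libraries. After thinning to 22817702 counts it had 9.34% more genes than the next library, which missed the bound of 10% written for this test. Depth is argued against on a ground added after that outcome, namely that the deepest library, with 38727047 counts, had 33272 genes. Genomic DNA stays open. The share of its reads outside genes, 17.6%, lay below the 4 control libraries with number 2 (21.1% to 21.8%) but above deletion clone 1 (17.1%). The bound first written, the highest of these libraries, was too loose to exclude it and was replaced after the outcome was seen. RNA of another cell type on the fixed marker lists was tested for lists with at least 3 silent markers. Microglial, mesenchymal, neuronal and glial markers had ratios to other silent genes of 0.741 to 0.889, which argues against those sources. For epithelium the ratio was 3.17, from 16 counts in 3 genes. That was under the bound written for this test but above the other silent genes, so epithelial RNA stays open. RNA of a source not on those lists also stays open, and no biological explanation was tested. Without this library the clone sums called 8480 genes.

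Other splits of the samples bear on whether the counts could come from grouping alone. With 15 ways to pick 2 of 6 clones the splits are too few for a share under 0.05. Among these, 1 of 15 splits reached the 9354 genes (highest other 0), 1 of 15 the 7 near genes (highest other 0), 1 of 15 the 2597 shared calls (highest other 738) and 2 of 15 the 16 lists (highest other 16). The counts that follow come from fits of only the libraries compared. For deletion clone 1, 1 of 100 splits of its 15 libraries gave as many as its 4536 genes (highest other 0). For deletion clone 2, 2 of 100 gave as many as its 3626 (highest other 3817). The higher split took 3 control libraries of number 3 and so followed the replicate number. Among splits with 1 library of each number the highest other was 0, and the blocked count was 8256. For neither deletion clone do these splits exclude chance, since they exchange wells, which are not separate clones. Splits that mix deletion and control wells also carry the difference between them into the spread. For the empty vector clone 4 of 100 splits of the control libraries gave as many as its 5 genes. That does not exclude chance here, since the splits exchange wells, which are not separate clones, and the fit of 18 libraries called 1 gene without any one of 5 libraries. Its highest other split, with 6611 genes, took 3 libraries of number 3 and points to a structure by replicate number, and the blocked count was 283. NTC1, NTC2 and NTC3 had 0 genes by edgeR, a count that any split reaches, so that 100 of 100 splits (highest other 6611) say nothing about them. Their blocked counts were 23, 16 and 0. For deletion clone 1 against deletion clone 2, 10 of 10 splits of 6 libraries gave 0 genes (highest other 0), and 10 splits are too few for a share under 0.05.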

How the results depend on the processing

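The tests within single replicate numbers, without number 3, without deletion clone 2 replicate 2 for the lists, and of the clone sums against a 1.5-fold change were chosen after seeing the data. TSPAN14 stayed lower and past the threshold under every alternative run, with log2 fold changes of -1.905 to -1.726 without single clones or libraries. The count of 9354 genes ranged from 6808 to 9305 without single clones or libraries, and moved to 6141 with 18 libraries as replicates, 5435 with one coefficient per clone, 5223 within number 1 and 1392 against a 1.5-fold change. The replicate block, which the pairing of numbers calls for, gave 10420 genes with one coefficient per clone. It moved deletion clone 1 to 9082, deletion clone 2 to 8256, their difference to 376, the empty vector clone to 283, NTC1 to 23, NTC2 to 16 and the shared calls to 6773. A 1.5-fold threshold gave 862, 680 and 3 genes for deletion clone 1, deletion clone 2 and their difference, 0 for the empty vector clone and 597 shared calls. Without a filter the difference of the deletion clones had 23 genes, the empty vector clone 42 and NTC2 1. DESeq2 gave 44, 29 and, for NTC1, 1. Fits of only the libraries compared gave 0 for the difference of the deletion clones and 5 for the empty vector clone. Without number 3 that difference had 6 genes. Leaving out single libraries gave 2630 to 4178 genes for deletion clone 1, 1963 to 3259 for deletion clone 2, 4 to 10 for their difference, 1 to 8 for the empty vector clone and 0 for each NTC clone by edgeR. The empty vector count of 1 came without its replicate 1 or 2, NTC1 replicate 2 or NTC3 replicate 2 or 3, and that of 8 without its replicate 3 or NTC1 replicate 1. The near genes numbered 6 to 7 without single clones and 4 with the clone as a random block. The lists numbered 15 to 18 without single clones, 15 without number 3 and 19 without deletion clone 2 replicate 2. They numbered 13 with the clone as a random block and 0 with an estimated correlation. The random block did not treat wells of one clone as alike. Without single clones or libraries EIF5AL1 ranged from -0.217 to 0.042 (without deletion clone 1), FAM213A from -0.11 to 0.033 (without deletion clone 2), with 0.028 without NTC1 and 0.004 without NTC1 replicate 1. DDIT4 ranged from -0.123 (without deletion clone 2 replicate 3) to 0.654 (without deletion clone 2 replicate 2), with -0.003 without deletion clone 1 replicate 3. Within number 2 alone ZCCHC24 was at 0.084, EIF5AL1 at 0.018, FAM213A at 0.087, DDIT4 at -0.457, MT-ND3 at -0.066 and MT-ATP6 at -0.189. Over all named genes and alternatives 4873 values kept direction and side of the threshold, 203 lost the threshold, 10 gained it and 12 reversed. For all of these the cause was not tested.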

Other observations

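The test on chromosomes 12 and 19 was chosen after the values had been seen.

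Of 18 targets of TGF-beta and SMAD, 9 fell and 4 rose (camera adjusted p = 0.0905, fry adjusted p = 0.00145). GREM1, a BMP antagonist, was 3.76-fold and the receptor TGFBR2 2.06-fold lower, while ID3 was 1.61-fold and BMP4 1.57-fold higher. Of 32 genes of the lysosome and of phagocytosis, 15 fell and 8 rose (camera adjusted p = 0.0905, fry adjusted p = 0.00883). In the astrocyte and oligodendrocyte list 4 of 10 fell and 1 rose (camera adjusted p = 0.0739, fry adjusted p = 0.00124), with the glutamate transporter SLC1A3 28.2-fold lower and ALDH1L1 3.51-fold higher. Of 8 neuronal genes 3 fell and 2 rose (camera adjusted p = 0.837, fry adjusted p = 0.286), with GAD1 2.03-fold higher. Cholesterol synthesis genes rose in 8 of 25 and fell in 3 (camera adjusted p = 0.363, fry adjusted p = 0.384), with DHCR7 1.46-fold higher. Of 23 p53 targets 5 fell and 1 rose (camera adjusted p = 0.352, fry adjusted p = 0.286), and of 24 genes of the unfolded protein and integrated stress response 5 fell and 2 rose (camera adjusted p = 0.988, fry adjusted p = 0.84).

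Of 14222 genes at 1 CPM or more in all 4 control clones, 12 had at most 3 counts in each deletion clone, 10 in deletion clone 1 alone and 3 in deletion clone 2 alone. By the same limits no gene was off in a control clone and on in the other 3, and none was on in both deletion clones and off in all 4 control clones. Independent loss would put 0.023 genes off in both if every gene were equally prone to it, which was not measured. The 12 include NUDT11 and BHLHE41, a transcription factor of the circadian clock, with 0 counts in both lines, as well as LAMP3, HOXC8 and FOXA3. These genes were named after their values were seen.

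Genes of chromosome 12 lay lower and genes of chromosome 19 higher in the deletion clones, along each whole chromosome. The median log2 fold change over 671 genes of chromosome 12 was -0.30 in each deletion clone, and over 867 genes of chromosome 19 it was 0.29 in clone 1 and 0.27 in clone 2. In the control clones these medians lay between -0.04 and 0.04. Running medians over 51 genes had the sign of the chromosome at 100% of positions in both lines. Chromosomes 9 and 14 also lay above 0 at 100% of positions in both lines, with smaller medians of 0.07 to 0.12. Chromosome 17 differed between the lines, with a median of -0.12 in clone 1 and 0.01 in clone 2. On chromosome 19 the running medians of NTC3 were also above 0 and those of NTC1 below 0 at 100% of positions, so the share of positions does not set the deletion clones apart there, and the size of the shift does. A candidate explanation is a change in the copy number of whole chromosomes that both deletion clones share, which is a hypothesis found and tested on the same counts. DNA copy number was not measured in the data used here. A trend with GC content, which differs between chromosomes, was not tested and stays open. Shared chromosome changes are what a common founder of both lines might leave, and they do not separate it from the deletion.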
